A study of Homo sapiens with 19 samples.

How the data were processed

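U2OS is an established human osteosarcoma cell line. The series holds 19 samples of these cells: 3 chromatin immunoprecipitations (ChIP) of EP400 with 3 inputs, ChIP of Pol II, the histone variants H3.3 and H2AZ, and the Mediator subunit MED26 after mock siRNA and after EP400 siRNA (1 library per antibody and condition), ChIP of the histone marks H3K18ac and H3K4me1 after mock siRNA (1 library each), 1 input after EP400 siRNA, and 1 RNA-seq library per condition. The mock siRNA was directed against GFP, and cells were harvested 72 hr after transfection, per the labels' protocols. The 4 inputs had no table of their own here and were not analysed here.

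The RNA values are FPKM (fragments scaled by transcript length and library size) for 48669 transcript rows with RefSeq identifiers, deposited by the authors with a lower and an upper confidence limit and a quantification status for each library, per the file headers. Per the submitters' processing notes, Bowtie 0.12.9, TopHat2 2.0.8, Cuffdiff 2.0.2 and the hg19 build were used. The annotation release and the normalization setting are not given in the sources used here. FPKM are not counts, and no total count came with them, so the sequencing depth is unknown and no count model was fitted. The deposited FPKM of all rows summed to 983896 in the mock library and 584131 in the EP400 siRNA library. A single row of 89 nt held 276908 and 155847 of these sums.

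Each ChIP file is a list of enriched regions deposited by the authors as chromosome, start and end, with no score or height, in steps of 50 bp for EP400 and 100 bp for the other antibodies. The peak caller, its threshold and its control library are not given in the sources used here. The 3 EP400 immunoprecipitations came as 1 list, and every other library as a list of its own. Peak numbers and widths depend on depth and enrichment, which such lists do not carry, so a list with fewer peaks can come from a shallower library. Coordinates are hg19, counted from 1.

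Gene symbols were assigned to 47555 of the rows (97.7%) by RefSeq identifier from a GRCh38 table that was used for names alone. Rows shorter than 200 nt (2116) were left out, a choice made after seeing that such a row had the highest FPKM of both libraries, and keeping them was tried as an alternative. The FPKM and the confidence limits of the remaining rows were summed per gene, and 122 of 24198 genes with a failed estimate were left out. Genes with a mean FPKM of 1 or more over both libraries were analysed (11671, of which 11408 had a symbol). The log2 ratio is log2 of (EP400 siRNA FPKM + 1) over (mock FPKM + 1), which understates the difference of low genes. A gene counted as different at a ratio of 2-fold or more. With 1 library per condition there is no replicate check, no test and no p-value for any RNA or ChIP comparison.

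The RNA table places each row in a locus, which is a cluster of overlapping transcripts without strand, and 3706 of 20850 loci (17.8%) hold more than 1 gene. A gene end is therefore the 2 kb on each side of either end of a gene's locus, in place of the gene start, so starts and ends of transcription are counted together, and neighbouring genes can share an end. Overlapping and antisense genes cannot be told apart. Enhancers are stretches shared by mock H3K4me1 and H3K18ac peaks, and a peak counted as an enhancer peak if it overlapped such a stretch and no gene end. Peaks were compared by overlap of 1 bp or more. A mock peak that overlapped a peak of the same antibody after EP400 siRNA is called retained. Chance overlap was measured by moving the peaks along their chromosomes by 100 offsets in steps of 20 kb up to 1 Mb on each side. Shares carry Wilson 95% confidence intervals, which cover counting error alone. Retention was also compared within 5 classes of peak width, because wide peaks were retained more often.

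The 25 gene lists were fixed before the data were examined and hold 545 entries, 543 of which matched a gene of the table. The median log2 ratio of each list was set beside 10000 random lists of the same size matched on mean FPKM in 20 bins, and a list below the 2.5 or above the 97.5 percentile was said to stand apart. This describes these 2 libraries. Local gene density is the number of loci within 500 kb of a gene's middle. The rule for named genes, also fixed before the data were examined, took EP400, the 12 genes with the highest and the 12 with the lowest log2 ratio among genes with a symbol and a mean FPKM of 5 or more, up to 4 members of each list with the largest log2 ratio in size, the 8 genes with the largest ratio in size that had an EP400 peak and lost H3.3 at their ends, and 6 genes at the widest EP400 peaks.

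The alternatives covered pseudocounts of 0.1 and 0.5, no filter on low values or a mean FPKM of 5 or more, median centring, rescaling of the FPKM to the same sum (TPM) in both libraries, gene ends of 1 kb and 5 kb, the wider 0.5 of each list with ties in width broken at random (many EP400 peaks share the shortest width of 50 bp), an overlap of at least 0.5 of the shorter peak, equal peak numbers taken by width, merging of peaks within 1000 bp, and enhancers by H3K4me1 alone. Others were added after seeing the data, among them centring within chromosomes and within groups of like local gene density, transcripts of every length, and failed estimates kept. On simulated FPKM for 11671 genes the size rule called 50 of 50 genes made 4-fold higher and 50 of 50 made 4-fold lower. It called 0 of 50 made 1.5-fold higher, 0 of 50 made 1.5-fold lower and 0 of 11471 unchanged genes. The altered genes all had a mock FPKM of 5 or more. The simulated noise was set far below the 2-fold rule, so these counts check the rule and give no error rate for the real libraries. Of 200 random lists, 13 (6.50%) stood apart, and 193 of 200 did so (96.5%) after their genes were raised by 1 on the log2 scale. These lists were drawn at random from all analysed genes, so the 6.50% need not hold for lists of related genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.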

Results

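EP400 is the SNF2-family ATPase of the TIP60-EP400 chromatin remodelling complex, which acts on the histone variants H2A.Z and H3.3. The data from U2OS cells comprised 1 list of 18048 EP400 peaks, lists of H3.3, H2AZ, Pol II and MED26 peaks after mock siRNA and after EP400 siRNA, lists of H3K18ac (55080 peaks) and H3K4me1 (49665 peaks) after mock siRNA, and RNA levels in both conditions. Each condition had 1 library per measurement, so no difference between conditions has a replicate check. The question named by the series title is whether EP400 places H3.3 at promoters and enhancers when genes are activated.

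EP400 mRNA, the target of the siRNA, stood at 10.04 FPKM in the mock library (the authors' confidence limits 0.165 to 19.9) and at 2.28 FPKM in the EP400 siRNA library (0.162 to 4.41). This is 22.8% of the mock level and a log2 ratio of -1.75, at a locus on chromosome 12 from 132434465 to 132565011. After rescaling to equal sums (TPM) the log2 ratio was -1.24. Among other genes of the TIP60-EP400 complex, DMAP1 (log2 ratio -1.18) and MRGBP (-1.06) were lower, as was the ATPase gene RUVBL2 (-1.03), whose sign turned on centring by local gene density or by chromosome. EP400 included, 4 of 16 measured members were at least 2-fold lower and 0 at least 2-fold higher, against 1 lower and 3 higher on median centring and 1 lower and 6 higher on rescaling. The list median of -0.17, which was above 0 under every other scaling tried, was within the range of matched random lists (percentile 80.9). Genes of the related SRCAP and INO80 remodelers had a median of -0.20 (percentile 58.7, 3 of 14 lower and 0 higher, but 0 lower and 5 higher on rescaling), which also turned above 0 on rescaling and on centring by density or chromosome.

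Among the genes with more RNA after EP400 siRNA were the secreted protease MMP3, at 1.55 FPKM in mock cells and 80.1 FPKM after EP400 siRNA, and ESM1, which encodes a secreted endothelial proteoglycan, at 0.171 and 32.0 FPKM. As deposited MMP3 had the highest log2 ratio (4.99, ESM1 4.82), and on rescaling ESM1 did (6.14, MMP3 5.99). Cytokine genes were also among the 12 highest: CXCL8, a neutrophil chemokine, went from 0.435 to 23.7 FPKM, IL24 from 0.984 to 33.97 FPKM, and CSF2, which encodes GM-CSF, from 5.45 to 70.6 FPKM. PTX3, BCL2A1, G0S2, OAS1, SCG5, IFIT3 and SLAMF9 completed the 12, with log2 ratios from 3.74 (PTX3) to 3.26 (SLAMF9). At the other end stood TNNC1, which encodes cardiac troponin C (156 FPKM in mock cells and 4.22 FPKM after EP400 siRNA), the endothelin gene EDN2 (44.0 and 0.768 FPKM) and LBH (83.8 and 3.75 FPKM). WFDC21P, SSC4D, CSDC2, DDAH2, ALPP, RARRES2, PDLIM1 and FOLR1 had log2 ratios from -3.96 (WFDC21P) to -3.49 (FOLR1). RPL21 was listed at 0 in the EP400 siRNA library beside 10.96 FPKM in mock cells, with an upper limit of 112, and is given without a fold.

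Of 11671 genes, 713 (6.11%) were at least 2-fold higher and 2677 (22.9%) at least 2-fold lower after EP400 siRNA. The balance differed with expression level and transcript length. In the lowest quintile of mean FPKM the median log2 ratio was 0.20 (102 higher, 163 lower), and in the highest -0.93 (65 higher, 1056 lower). For the shortest quintile of transcripts it was -0.57 (91 higher, 715 lower), and for the longest 0.06 (124 higher, 303 lower). The cause of these trends was not tested, and a difference between the libraries is not excluded. The balance also depended on scaling. Median centring, which removes the median log2 ratio of -0.20, gave 1260 higher and 1825 lower genes, and rescaling to equal sums (TPM), which shifted the median gene by 0.68, gave 3700 higher and 696 lower. Centring by local gene density gave 1019 higher and 1265 lower genes, and centring by chromosome 1162 and 1575. The log2 ratios of the 12 highest and the 12 lowest genes kept their sign under each of these scalings. The authors' confidence limits, summed over the transcripts of each gene, were wide, with an upper limit at the median gene 119.7% above the FPKM in mock cells. The summed limits were apart for 10 of the higher and 15 of the lower genes. Summing can overstate the spread of a gene with several transcripts, which may hold these counts down.

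Interferon response genes were higher as a group. Of 22 measured members 15 were at least 2-fold higher and 0 at least 2-fold lower, and the median log2 ratio was 1.33, which was 1.67 above matched random lists (percentile 100). OAS1, a sensor of double-stranded RNA, went from 1.39 to 23.6 FPKM, IFIT3 from 1.78 to 26.3 FPKM, OASL from 8.40 to 75.6 FPKM and IFI6 from 109 to 737 FPKM. Inflammatory genes controlled by NF-kB had a median of 0.73, with 6 of 14 at least 2-fold higher and 1 lower, among them CXCL3 (log2 ratio 3.13) and the chemokine CCL20 (2.43). This list lay 1.04 above matched lists (percentile 100), and at a mean FPKM of 5 or more the percentile was 96.7, short of standing apart.

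Stress and growth genes also lay above matched lists. Genes of the unfolded protein and amino acid response had a median log2 ratio of 0.80 (7 of 20 at least 2-fold higher and 2 lower, 10 and 0 on median centring, 16 and 0 on rescaling), with the transcription factor DDIT3 at 2.09, asparagine synthetase ASNS at 1.88, the ER chaperone HSPA5 at 1.48 and XBP1 at 1.24. Heat shock genes split: HSPD1 (1.88), HSP90AA1 (1.80) and HSPA8 (1.61) were among 5 of 14 higher genes, and the small heat shock gene HSPB1, at 1799 FPKM in mock cells and 238 FPKM after EP400 siRNA, was among 4 lower genes, with a list median of 0.72 (8 higher and 1 lower on rescaling). MYC targets and ribosome biogenesis genes had a median of 0.58 (5 of 28 higher and 2 lower, 11 and 2 on median centring, 15 and 0 on rescaling), with NOP58 at 1.46 and MYC at 1.33 beside CAD at -1.28 and CDK4 at -1.24. Immediate-early genes (median 0.21, 1 of 14 higher and 1 lower, 4 and 1 on median centring, 7 and 0 on rescaling, with CCN2 at 1.15 and NR4A1 at -1.22) and housekeeping genes (median 0.19, 1 of 14 higher and 3 lower, but 7 higher and 0 lower on rescaling) stood apart as well (percentiles 99.5 and 99.98).

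Genes of DNA replication (median 0.07, 6 of 35 lower and 0 higher, but 2 lower and 14 higher on rescaling) and mitosis (median -0.01, above 0 on median centring and rescaling, 7 of 29 lower and 0 higher, but 1 lower and 7 higher on rescaling) lay above matched lists by 0.70 and 0.59, although their named members TK1 (-1.97), E2F2 (-1.97), CENPA (-1.85) and PLK1 (-1.63) were lower. Ribosomal protein genes had a median of -0.59 (19 of 58 lower, 0 higher) and oxidative phosphorylation genes of -0.30 (9 of 35 lower, 0 higher), both above matched lists, by 0.36 and 0.55. Both medians changed sign after rescaling to equal sums (TPM), to 0.17 and 0.45, and the counts turned to 0 lower and 3 higher for ribosomal protein genes and 0 lower and 9 higher for oxidative phosphorylation genes. None of these 4 lists stood apart once ratios were centred within groups of local gene density, a check added after seeing the data. The mitosis list also lost its call at a mean FPKM of 5 or more (percentile 95.55) and on centring by chromosome (percentile 83.2), and the ribosomal protein list on centring by chromosome (percentile 94.8). Epithelial markers, a list kept as a check for other cell types, were below matched lists: the median of 4 measured genes was -1.77 (percentile 0.19), with CLDN4 at -2.44 and KRT14 at -1.86. That call was also lost on centring by local gene density (percentile 7.90) and at a mean FPKM of 5 or more (percentile 2.55).

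**Figure D1:**
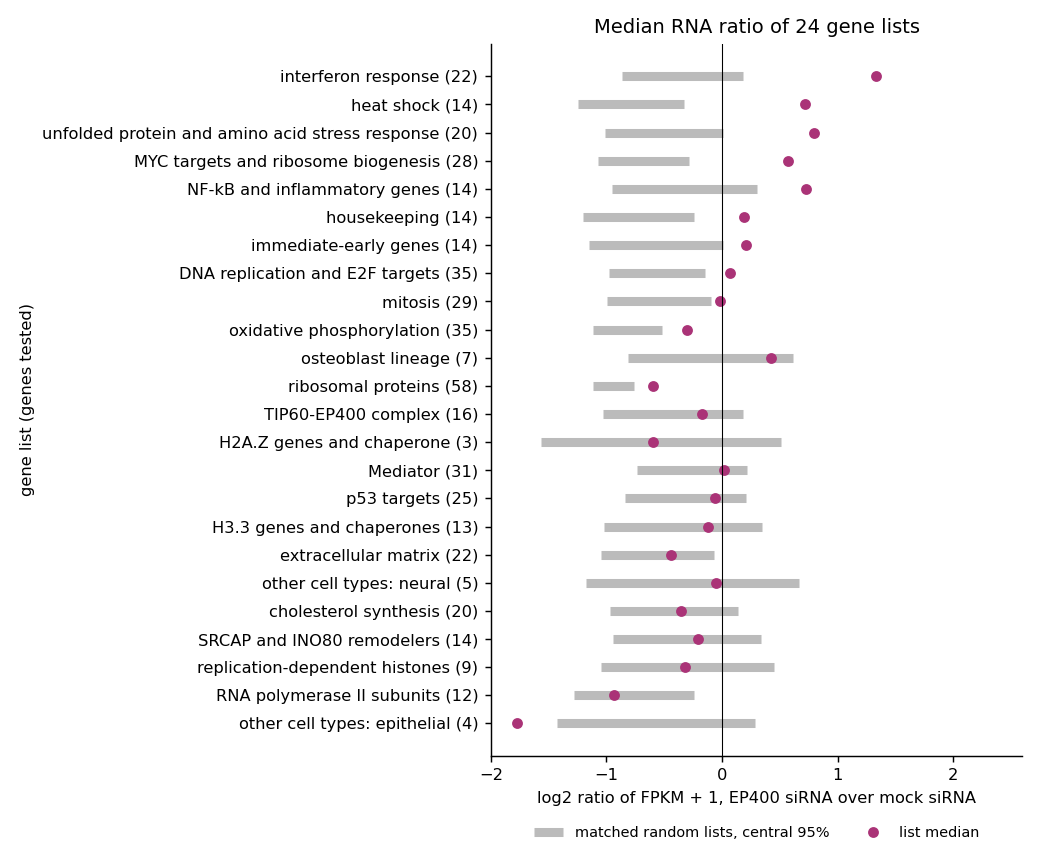
Median log2 RNA ratio (x axis, EP400 siRNA over mock siRNA, FPKM + 1) of 24 gene lists (y axis, with the number of genes measured); points are list medians and grey bars the central 95% of 10000 random lists matched on expression. The interferon list at 1.33 lies farthest above its grey bar, and the epithelial list at -1.77 is left of its own.

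Genes coding for the histone machinery did not stand apart. H2AZ1 and H2AZ2, which encode H2A.Z, had log2 ratios of -0.59 and -0.88, and the H2A.Z chaperone gene ANP32E -0.48. For H2AZ1 and ANP32E the sign turned after rescaling to equal sums (TPM) (0.18 and 0.23), and for ANP32E also on centring by local gene density (0.46). The list of these 3 genes had a median of -0.59 (percentile 66.0), which also turned on rescaling (0.18). H3-3A, a gene for H3.3 with near-identical copies elsewhere that may make its estimate uncertain, stood at 4.01 and 0.880 FPKM. The authors' limits were wide, at 0 to 22.8 and 0 to 13.5 FPKM. Of 13 measured genes for H3.3 and its chaperones 3 were at least 2-fold lower, including ASF1B at -1.47, and 0 higher (1 lower and 3 higher on rescaling), and the median of -0.12 (percentile 71.6) was above 0 under every other scaling tried. Pol II subunit genes had a median of -0.94 (5 of 12 lower, 0 higher), close to matched lists at -0.88 (percentile 40.7). On rescaling their median was -0.18 with 0 lower and 3 higher, and on centring by local gene density -0.18 with 0 lower and 0 higher. Mediator genes had a median of 0.02 (percentile 85.7, 2 of 31 higher and 4 lower, but 9 higher and 0 lower on rescaling), which was -0.04 on centring by local gene density. Replication-dependent histone genes had a median of -0.32 (percentile 47.4, 1 of 9 higher, 1 lower), which was above 0 on rescaling (0.24) and on centring by local gene density (0.52).

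EP400 was enriched at gene ends and enhancers. Of 18048 EP400 peaks, 5146 (28.5%, confidence interval 27.9 to 29.2%) lay within 2 kb of a gene end, against a mean of 6.97% and at most 8.51% for moved peaks. Another 772 (4.28%) lay at enhancers away from gene ends, and 12130 (67.2%) elsewhere. The widest EP400 peak spanned 1400 bp (chromosome 2, 70313551 to 70314950) at an end of PCBP1, which encodes a poly(C)-binding protein. It also lay at an end of the locus that PCBP1-AS1 and ASPRV1 share (70187224 to 70314147). The peak therefore need not lie at ASPRV1 itself. The next peaks by width at gene ends lay at EIF3B (chromosome 7, 2393551 to 2394850) and at the neighbouring ends of CBX3 and HNRNPA2B1 (chromosome 7, 26240851 to 26242100). RNA of EIF3B went from 259.6 to 364 FPKM and that of PCBP1 from 395 to 204 FPKM. Highly expressed genes carried EP400 more often: 6.53% of genes in the lowest quintile of mock FPKM had an EP400 peak at an end and 43.5% in the highest.

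EP400 peaks coincided with other factors. In mock cells 27.9% overlapped H3K18ac, 25.5% Pol II, 22.1% MED26, 17.4% H2AZ, 10.4% H3.3 and 7.40% H3K4me1. The highest shares of moved peaks were 3.41% for H3K18ac, 1.99% for Pol II, 1.15% for MED26, 1.32% for H2AZ, 3.18% for H3.3 and 1.72% for H3K4me1. In all, 54.8% of EP400 peaks overlapped no peak of any other list, those after EP400 siRNA included. Among the gene lists, ribosomal protein genes had an EP400 peak at an end in 48 of 58 cases and mitosis genes in 20 of 29. Interferon genes had one in 5 of 22 and extracellular matrix genes in 4 of 22, beside 36.1% of all genes. Expression level, with which EP400 at gene ends climbed, was not held equal between the lists.

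After EP400 siRNA the H3.3 list held 41439 peaks against 79838 in mock cells, and the H2AZ list 26526 against 58082. Pol II peaks numbered 20987 against 30760 and MED26 peaks 24366 against 27006. Of mock H3.3 peaks 5.01% (4.86 to 5.16%) were retained, above the highest moved share of 1.97%. H2AZ peaks were retained in 28.1%, Pol II peaks in 48.2% and MED26 peaks in 49.0%. Seen from the other list, 10.5% of the H3.3 peaks after EP400 siRNA overlapped a mock peak, compared with 65.1% for H2AZ, 73.5% for Pol II and 56.2% for MED26. Depth and enrichment differ between libraries to an unknown degree, and with equal peak numbers in both lists H2AZ retention was 49.8% and H3.3 retention 8.41%.

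At EP400 peaks each of these factors was listed less often after EP400 siRNA. H3.3 overlapped 1885 EP400 peaks in mock cells and 691 after EP400 siRNA, H2AZ 3148 and 1188, Pol II 4601 and 3502, and MED26 3989 and 3194. At gene ends H3.3 overlapped 935 and 188 of them, H2AZ 2043 and 849, Pol II 3488 and 2794, and MED26 2976 and 2479. Of the 772 EP400 peaks at enhancers, H3.3 overlapped 276 and 74, H2AZ 112 and 11, Pol II 100 and 22, and MED26 103 and 43. The lists were also shorter irrespective of EP400, with 20961 and 6230 H3.3 peaks, 17047 and 10654 H2AZ peaks, 15682 and 13183 Pol II peaks and 13213 and 12022 MED26 peaks at gene ends. At enhancers there were 7919 and 1359 H3.3 peaks, 2838 and 467 H2AZ peaks, 2256 and 273 Pol II peaks and 2718 and 1390 MED26 peaks. Counts of EP400 peaks overlapped and counts of factor peaks are on different scales, so these numbers alone do not separate EP400 sites from other sites.

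**Figure D2:**
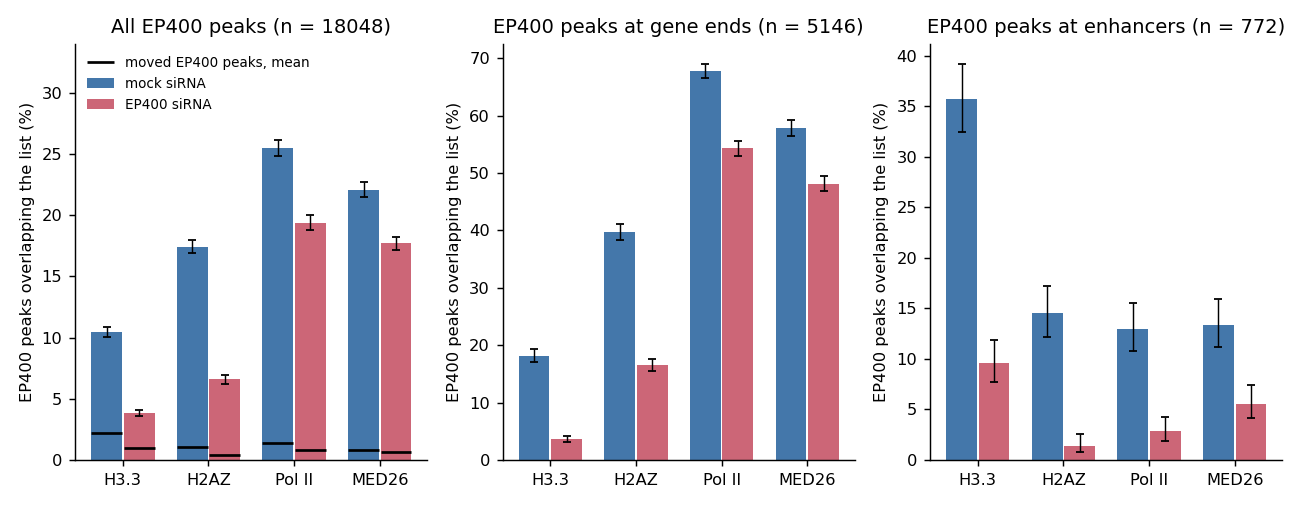
Share of EP400 peaks (y axis, %) that overlap a peak of H3.3, H2AZ, Pol II or MED26 (x axis) after mock siRNA (blue) and EP400 siRNA (red), for all EP400 peaks, those at gene ends and those at enhancers; error bars are Wilson 95% intervals for counting error and black lines the mean of moved EP400 peaks. All red bars are below their blue bars, with H3.3 at gene ends at 18.2% and 3.65%.

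Peaks with EP400 were nonetheless retained more often than peaks without it. For H3.3 the shares were 17.9% of 1815 mock peaks with EP400 and 4.71% of 78023 without, for H2AZ 54.5% and 26.7%, for Pol II 91.6% and 42.2%, and for MED26 89.6% and 43.2%. EP400 lay at wider peaks, with a median of 1400 bp against 400 bp for Pol II. Within classes of width the mean difference was 6.47 percentage points for H3.3, 5.60 for H2AZ, 3.24 for Pol II and 6.85 for MED26, down from 13.1, 27.9, 49.4 and 46.3 without classes. Each class counted alike in these means, and for Pol II the classes ranged from -9.09 points at 200 bp, with 32 EP400-bound peaks, to 12.6 points at 500 to 900 bp. Chromosome and local gene density were not held equal. The ratio of H3.3 peak numbers was lowest on chromosome 19 (0.115), which held 2.13% of EP400 peaks. It was highest on chromosome 4 (1.73), which held 8.78%. The difference for H3.3 is therefore not separated from the place of EP400 peaks in the genome.

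**Figure D3:**
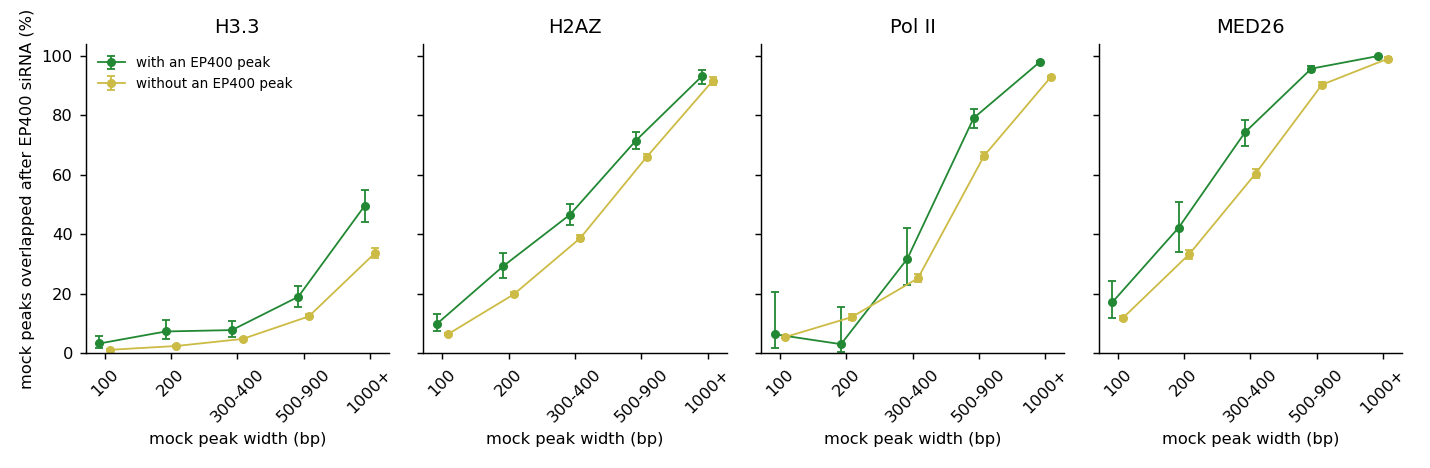
Share of mock peaks overlapped by a peak of the same antibody after EP400 siRNA (y axis, %) by mock peak width (x axis, bp), for peaks with (green) and without (yellow) an EP400 peak; error bars are Wilson 95% intervals. Retention climbs with width for each antibody, except for a dip among 32 Pol II peaks of 200 bp with EP400, and H3.3 peaks of 1000 bp or more were retained in 49.6% of cases with EP400 and 33.8% without.

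Enhancer peaks of Pol II, H2AZ and MED26 were retained less often than those at gene ends. Pol II peaks were retained in 68.5% of cases at gene ends and in 19.2% at enhancers, H2AZ peaks in 47.4% and 18.7%, and MED26 peaks in 66.9% and 35.0%. H3.3 differed: 7.10% (6.76 to 7.46%) at gene ends and 9.47% (8.85 to 10.1%) at enhancers. Within classes of width the difference was 30.7 percentage points for Pol II, 26.5 for H2AZ and 16.5 for MED26 (gene ends minus enhancers). For H3.3 it was -0.375, so most of the difference for H3.3 went with peak width.

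Genes with EP400 at an end differed little in RNA. The 4207 such genes had a median log2 ratio of -0.19, against -0.34 for matched random lists (percentile 100). The difference of 0.15 shrank to 0.09 on centring by local gene density and to 0.10 with gene ends of 5 kb. Of the genes with EP400 22.8% were at least 2-fold lower compared with 23.03% of the 7464 genes without EP400. Genes that lost H3.3 at their ends (4784 of 8209 with a mock peak) had a median of -0.62, a difference of -0.20 from matched genes (percentile 0), and those that lost H2AZ (2591) had a median of -0.46, also -0.20 from matched genes. Genes that lost MED26 (712) differed from matched genes by -0.30. Centring by local gene density shrank these differences to -0.09 for H3.3, -0.03 for H2AZ (percentile 1.75) and -0.18 for MED26. The difference for H3.3 was also smaller at gene ends with H3K18ac (-0.11), where that for MED26 was larger (-0.43), and that for H2AZ at a mean FPKM of 5 or more (-0.12). Loss of Pol II (782 genes) did not stand apart (0.06 above, percentile 92.7), but did at a mean FPKM of 5 or more (0.24 above) and on the same centring (0.11 above). H3.3 was lost from 46.5% of genes with EP400 and 67.3% of genes without it. Expression level, peak width and chromosome were not held equal in that comparison.

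Of the 8 genes with EP400 that lost H3.3 and differed most in RNA 7 were lower after EP400 siRNA, where all genes that lost H3.3, with or without EP400, counted 1507 at least 2-fold lower and 195 higher. MXD3, of the MAX dimerization network that opposes MYC, went from 82.7 to 7.66 FPKM, SAMD11 from 15.8 to 1.17 FPKM, HSPB1 from 1799 to 238 FPKM and MYL9, a myosin light chain gene, from 216 to 30.0 FPKM. ENO3, JUP and GPR162 had log2 ratios of -2.67, -2.55 and -2.52. The interferon gene OASL, at 3.03, was the exception among these 8. EP400 and H3.3 were assigned by the ends of a locus, which can hold other genes. The locus of MYL9, for example, ran from 34894245 to 35201678 on chromosome 20. For such a gene the peaks may belong to a neighbour.

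Chromosomes differed in both RNA and H3.3. Genes of chromosome 19 had a median log2 ratio of -1.05, those of chromosome 22 of -0.89 and those of chromosome 16 of -0.78, whereas chromosome 18 stood at 0.34 and chromosome 4 at 0.27. H3.3 peaks on chromosome 19 numbered 6178 in mock cells and 710 after EP400 siRNA (log2 ratio -3.12), and on chromosome 4 they numbered 1425 and 2467 (0.79). H2AZ peak ratios ranged from -1.42 to -0.92 over the chromosomes, those of Pol II from -0.93 to -0.24 and those of MED26 from -0.31 to 0.04. From the lowest to the highest quintile of local gene density the median RNA ratio went from 0.33 to -0.99, with 1148 genes of the highest quintile at least 2-fold lower and 42 higher.

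**Figure D4:**
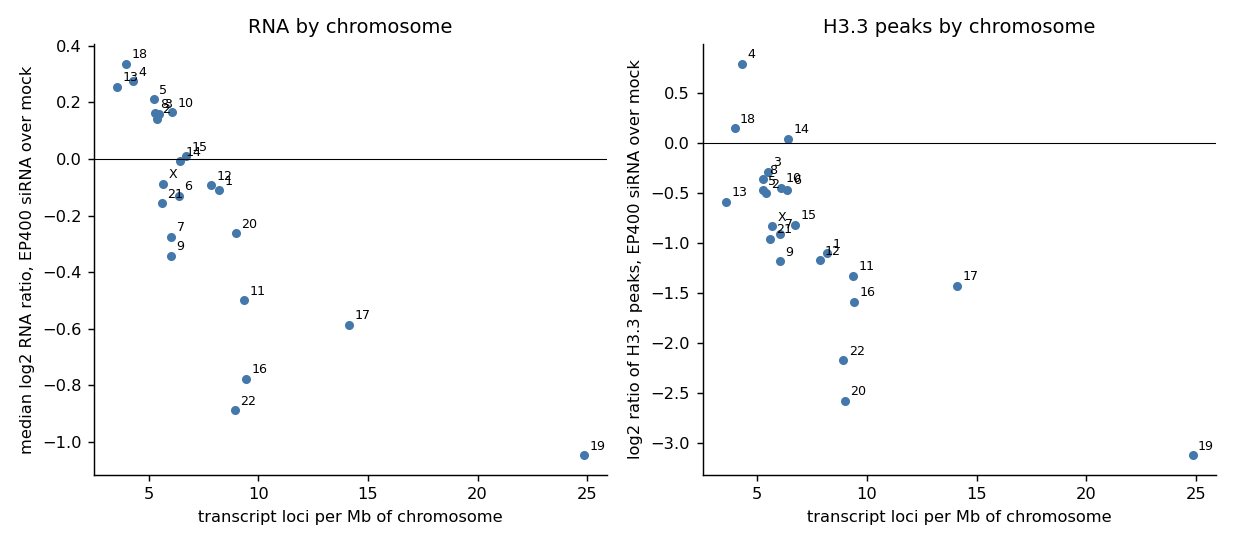
Median log2 RNA ratio of the genes of each chromosome (left) and log2 ratio of the number of H3.3 peaks (right), EP400 siRNA over mock siRNA, against transcript loci per Mb (x axis); each point is a chromosome, labelled by its name. Chromosome 19, with 24.8 loci per Mb, is lowest in both panels at -1.05 and -3.12.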

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

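Centring on each chromosome or by local gene density, rescaling for the gene lists, transcripts of every length, failed estimates kept, non-overlapping confidence limits, ends of single-gene loci, ends with H3K18ac, and the width strata for gene ends against enhancers were chosen after seeing the data. No paired analysis was possible because the EP400 immunoprecipitations and inputs I to III, which share replicate numbers, come as 1 peak list, and every other group has 1 sample. Of the results that answer a comparison 68 values stayed within their bounds (some by construction, such as list calls on median centring, the gene-end share with another enhancer definition, and the enhancer share at ends with H3K18ac), 70 moved beyond them and 2 went past a threshold. Depth is unknown for each library and limits every count of peaks. Except where a setting changes the genes or peaks counted by its own construction, the cause was not tested.

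Higher genes numbered 1316 with a pseudocount of 0.1, 417 at a mean FPKM of 5 or more, 1260 on median centring, 3700 on rescaling to equal sums, 1162 on centring by chromosome, and 10 where confidence limits had to be apart. Lower genes numbered 696 on rescaling, 1575 on centring by chromosome, 1265 on centring by density and 15 with limits apart. Lists above matched lists numbered 7 on centring by density, and lists below numbered 0 at a mean FPKM of 5 or more. The extracellular matrix list reversed on centring by density, to -0.41 relative to matched lists (percentile 1.12, past the threshold), and was then the 1 list below matched lists in place of the epithelial list. Median centring subtracts 1 value from every gene and so cannot change a list's place among matched lists. Rescaling, by 1 factor per library, can do so only through the pseudocount, since the filter used the FPKM before rescaling. Of the 24 list medians 24 kept their call with a pseudocount of 0.1, 21 at a mean FPKM of 5 or more, 22 on centring by chromosome and 18 on centring by density.

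The share of EP400 peaks at gene ends was 22.9% with ends of 1 kb, 36.3% with ends of 5 kb, 35.9% for the wider peaks, 24.2% at ends with H3K18ac and 23.04% at single-gene loci. The enhancer share was 3.83% with ends of 5 kb, 4.71% for the wider peaks and 6.36% with enhancers by H3K4me1 alone. With every list cut to its wider 0.5, EP400 overlapped H2AZ in 19.4%, Pol II in 34.3% and MED26 in 30.5%. On the same cut it overlapped H3K18ac in 31.2% and H3K4me1 in 6.29%. These shares reflect the shortened lists of the other antibodies as well as the width of EP400 peaks. An overlap of 0.5 of the shorter peak gave 9.996% with H3.3, 16.8% with H2AZ and 27.3% with H3K18ac. The gap in EP400 between the outer quintiles of expression was 33.4 points with ends of 1 kb and 29.0 points for the wider peaks.

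Retention with an overlap of 0.5 of the shorter peak was 4.74% for H3.3, 27.6% for H2AZ and 48.4% for MED26. With both lists cut to their wider 0.5 it was 5.55% for H3.3, 32.5% for H2AZ, 62.6% for Pol II and 68.8% for MED26. Equal peak numbers gave 8.41% for H3.3, 49.8% for H2AZ, 67.4% for Pol II and 53.1% for MED26, and merging gave 8.25%, 31.7%, 56.7% and 55.2% in the same order. The difference in retention between peaks with and without EP400 was 23.7 points for H3.3, 36.8 for H2AZ, 41.7 for Pol II and 44.9 for MED26 on merging. With every list cut to its wider 0.5 it was 15.5 for H2AZ, 23.2 for Pol II and 26.2 for MED26. Within width strata it was 6.47 for H3.3, 5.60 for H2AZ, 3.24 for Pol II and 6.85 for MED26.

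Retention at gene ends minus enhancers was -1.38 points for H3.3, 31.5 for H2AZ, 56.9 for Pol II and 36.7 for MED26 with ends of 1 kb. With ends of 5 kb it was -3.30, 25.1, 42.8 and 27.4 in the same order, and within width strata -0.375, 26.5, 30.7 and 16.5. With enhancers by H3K4me1 alone it was 26.9 for H2AZ and 34.9 for MED26. Genes that lost Pol II lay 0.24 above matched genes at a mean FPKM of 5 or more and 0.11 above on centring by density, both past the upper percentile.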

Other observations

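Chosen after the result was seen were the tests on base composition, on the H3.3 peaks, on the interferon and inflammatory lists and on Pol II coverage. Targets of p53 had a median log2 RNA ratio of -0.06 (percentile 80.5, 1 of 25 at least 2-fold higher and 7 lower, but 9 higher and 3 lower on rescaling), which was above 0 on median centring, on rescaling and on centring by chromosome. The apoptosis gene PMAIP1 stood at 2.52, while FDXR (-2.30), PHLDA3 (-1.82) and BBC3 (-1.80) were lower. Cholesterol synthesis genes had a median of -0.36 (0.35 on rescaling to equal sums, percentile 60.2, 1 of 20 higher and 7 lower, 3 higher and 4 lower on rescaling), with the regulator SREBF2 at -2.07. Extracellular matrix genes had a median of -0.44 (0.29 on rescaling, percentile 74.9, 5 of 22 higher, 6 lower), with the collagen gene COL1A1 at -2.61 and fibronectin, FN1, at 1.72. On centring by local gene density this list stood apart below matched lists (percentile 1.12, 4 higher, 9 lower). Osteoblast genes had a median of 0.42 (percentile 88.7, 2 of 7 higher, 1 lower), with BMP4 at -2.23 and TNFRSF11B at 2.17. Neural markers had a median of -0.05 (percentile 60.5, 1 of 5 higher, 1 lower), which was above 0 on median centring, rescaling and centring by chromosome. Of 12 blood markers 2 were measured, CD68 and CD34, and 0 differed by 2-fold.

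The 1 Mb window with the most EP400 peaks lay on chromosome 4 (30000001 to 31000000, 92 peaks), followed by chromosome 18 (2000001 to 3000000, 73 peaks). Across 2885 windows of 1 Mb, which are not independent, Spearman's rho of EP400 peak number with H3.3 peak number was 0.68 in mock cells and 0.81 after EP400 siRNA, the highest of the 10 lists. For H2AZ it was 0.70 and 0.65. Overlap of single peaks with H3.3 went the other way, from 10.4% of EP400 peaks in mock cells to 3.83% after EP400 siRNA. The H3.3 list was also shorter then. A higher rho over 1 Mb windows thus does not mean that more EP400 and H3.3 peaks shared a site. Its cause was not tested. Over 23 chromosomes, which are not independent replicates, the RNA median went with the Pol II peak ratio (Pearson's r 0.54, Spearman's rho 0.57, r 0.64 without the 2 farthest), and rho was -0.30 for H2AZ and -0.27 for MED26.

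RNA was lower after EP400 siRNA in gene-rich than in gene-poor regions, with a gap of -1.32 in median log2 ratio between the outer quintiles of local gene density. Within quintiles of expression level the mean gap was -1.08, and within quintiles of transcript length -1.28, so neither accounts for it. Among genes bound by EP400 the gap was -1.36, and among genes without an EP400 peak -1.28, which argues against binding at gene ends as the source. Over 23 chromosomes, which are not independent replicates, the RNA median went with the H3.3 peak ratio (Pearson's r 0.84, Spearman's rho 0.87, r 0.73 without the 2 farthest chromosomes). Base composition of the libraries cannot be told apart from gene density, since no genome sequence was used here, and it may act on both RNA and H3.3 (rho 0.87).

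H3.3 peaks after EP400 siRNA lay mostly at other places than in mock cells. Of those without a mock peak 12.6% were at gene ends, above the highest moved share of 7.81%. This argues against peaks placed without regard to gene ends as the whole list. Background raised at gene ends was not tested. The same share was 21.9% for H2AZ, 38.2% for Pol II and 27.1% for MED26. Weaker signal at the same places would leave peaks that overlap mock peaks, and 10.5% did. Mock H3.3 peaks of 1000 bp or more were retained in 49.6% of cases with EP400 and 33.8% without. Weaker signal is therefore not excluded. Loss where EP400 binds would spare mock H3.3 peaks without EP400, and 4.71% of these were retained. A difference in quality between the 2 H3.3 libraries was not tested, and with 1 library each no value separates it from the siRNA.

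The interferon list lay above matched lists after EP400 siRNA, as did the inflammatory list, with 6 of 14 genes at least 2-fold higher and a call lost at a mean FPKM of 5 or more (percentile 96.7). Centring by local gene density left the interferon list 1.74 and the inflammatory list 0.85 above matched lists, which argues against local gene density for both. Of the 21 higher members of the lists 4 had EP400 peaks at their ends (19.0%, interval 7.67 to 40%), beside 36.1% of all genes, and with so few members a role of EP400 there cannot be told apart from none. A response to the siRNA itself may contribute and cannot be told apart from loss of EP400, as there was no library with another EP400 siRNA. The mock library had an siRNA against GFP, so a response shared by both siRNAs would not appear as a difference.

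A further hypothesis was that genes with more RNA also have more Pol II peak coverage. More Pol II coverage was found at 7.29% of the higher genes and 7.77% of the lower genes, so gains did not follow RNA. The Pol II list was shorter after EP400 siRNA (20987 peaks against 30760), which limits gains in any group. Among genes with a Pol II peak in either condition, 84.5% (81.5 to 87.2%) of 620 higher genes had less coverage. For 2588 lower genes the share was 89.4% (88.1 to 90.5%), so losses were slightly more frequent among lower genes. For H3.3, 40.7% of higher genes had more and 42.1% less coverage after EP400 siRNA, compared with 2.65% and 89.4% of lower genes. Within quintiles of local gene density the mean gap was 28.2 points, which argues against local gene density shared by both as the whole link. Expression level, chromosome and H3.3 in mock cells were not held equal, and base composition was not examined. In mock cells 87.2% of lower genes had an H3.3 peak at an end, against 56.7% of higher genes. After EP400 siRNA these shares were 32.2% and 40.3%. Lower genes thus had more H3.3 to lose, and a separate link between RNA and H3.3 is not shown.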
